A study of Rattus norvegicus with 12 samples.

How the data were processed

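Rat epidermal keratinocytes of the REK line were grown without feeder cells as organotypic cultures on a collagen-coated insert and raised to the air-liquid interface. The sample records describe 4 groups of 3 cultures: mock-irradiated control, 10 mM betaine, 30 mJ/cm2 UVB, and betaine with UVB. Betaine was present for 11 days, and UVB was given 24 h before collection, when the cultures were 2 weeks old. The epidermal layer was taken off the insert, and 400 ng of total RNA per culture was labelled with biotin, hybridized to the Illumina RatRef-12 BeadChip and stained with Cy3-streptavidin, per the sample records. The records do not state if the 3 cultures of a group came from separate experiments, so the p-values measure only the spread between these samples.

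The deposited table of non-normalized data holds, per the file headers, an average signal intensity for each of 22523 probes on each of 12 arrays. These intensities are not background-subtracted; the software that exported them is not named in the sources used here. Beside each intensity the file headers give a detection p-value, whose values move in steps of 1 in 825. The processed values deposited by the authors, taken as log2 from their range, were normalized between arrays by a method that is not stated. They keep the rank order of the intensities within each array (rank correlation 1), and their array medians are all 7.71. Of the probes, 174 lack an authors' processed value. The submitters' notes name R 2.11 and limma without giving the role of either. Every column of the deposited table was used, as signal or as detection p-value.

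Before the data were examined, the groups, the comparisons, the filter, the thresholds, the gene lists and most alternatives were chosen from the sample records and the platform alone. Intensities were background-corrected and quantile-normalized with the neqc function of limma 3.58.1 in R 4.3.3, with negative-control levels inferred from the detection p-values and an offset of 16, and are given as log2 values. Raw array medians ran from 95.9 to 117.7. A probe was kept with a detection p-value under 0.05 on at least 3 of the 12 arrays; 10369 to 10768 probes per array were detected at that level, 46.0 to 47.8 percent. With a gene name required, 11255 probes were kept and 11268 left out, and 10937 genes were tested with 1 probe each, the probe with the highest mean.

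Gene names were updated with a table of rat genes (GRCr8), used for names only; no sequence was aligned. The table matched 16911 probes: 10291 by current symbol, 1642 by gene ID and 4978 by an older synonym. A further 5495 probes kept the name given with the array, and 117 had none. Names reached through a synonym are less certain; among the genes named in the text these are Pclaf, Orc1, Mis18a, Cdk14, Bbs9, Ces1d, Cox8b, Cdt1, Il36a, Tbc1d25, Zfp775, Krt36, Vopp1 and Ccn2. Bcas3, Plet1, Ranbp3l and Tmem121b were reached through the gene ID.

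All 12 arrays entered 1 linear model in limma with a mean per group, empirical Bayes moderation (8 residual and 3.83 prior degrees of freedom) and no pairing of cultures. Comparisons were UVB vs control, betaine vs control, betaine + UVB vs UVB, betaine + UVB vs betaine, betaine + UVB vs control, the interaction (the UVB effect with betaine minus the UVB effect without it), UVB averaged over the betaine states and betaine averaged over the UVB states. P-values were adjusted by Benjamini-Hochberg over all tested genes within a comparison, and a gene counted as changed at an adjusted p under 0.05. Values after ± beside a change are standard errors from the model with 3 arrays per group; the median standard error was 0.12 log2 for a comparison of 2 groups, 0.17 for the interaction and 0.086 for an averaged effect.

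The 24 gene lists were written from general knowledge before the data were examined, and the 18 with at least 5 measured members were tested: p53 targets, nucleotide excision repair, DNA replication, mitosis, inflammatory mediators, interferon-stimulated genes, cornified envelope and late differentiation, basal layer, NRF2 and antioxidant, heat shock and unfolded protein response, osmolyte transport and betaine metabolism, methionine and one-carbon metabolism, hyaluronan, EGF ligands and immediate early genes, cholesterol synthesis, barrier lipids, proteases and matrix remodelling, and ribosomal proteins. Lists were compared with all other genes by the camera test, with a preset correlation between genes of 0.01 and again with the correlation estimated from the residuals; list p-values are adjusted over the tested lists of a comparison. Where the median, the mean and the test of a list differ in sign, the list had no call; in UVB vs control these are p53 targets, NRF2 and hyaluronan. Wound and stress keratins and 5 lists of markers of other cell types had too few members and are described only.

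Genes are named by rule. UVB vs control names up to 12 of the largest rises and 12 of the largest falls among called genes whose arrays do not overlap between the groups, and the other comparisons of 2 groups name up to 8 each way, except betaine + UVB vs control. The averaged effects name up to 8 each way without the overlap condition. With fewer than 10 calls, the 5 lowest p-values in each direction are given as values without a call. Non-overlap of 3 arrays with 3 others occurs by chance in 10 percent of genes. Placeholder locus names are counted and not named, up to 4 members per list are named by the size of their t statistic, and Krt2, Slc6a12, Bhmt and Cdkn1a are always given. Where a gene was undetected in every array of its dimmer group, the fold change is stated as a lower bound: the brighter group against the higher, on each array, of the probe's own signal and the lowest signal among detected probes. Averaged effects use the same rule for each group undetected on every array, except for Adm2, whose averaged sizes are marked as not exact. These bounds hold for the background correction used.

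Alternatives were no background correction, normexp correction without negative controls, cyclic loess, median scaling, the authors' processed values, no filter, a stricter filter, every probe on its own, an intensity trend with robust spread, array weights, a replicate block, models with only the groups compared, adjusted p under 0.01, a fold of at least 1.5, and each array left out in turn. In a simulation of 11100 genes on the same layout, with known changes added to some genes, UVB vs control called 93.9 percent of genes raised by 2 log2 units, 72.7 percent raised by 1 and 36.4 percent raised by 0.5. Genes lowered by 2 units were called in 48.5 percent, since some then reached background. In the interaction, changes of 1 unit upward were called in 48.5 percent and of 0.5 in 12.1 percent. Of 10674 unchanged simulated genes, 11 were called in UVB vs control and 6 in the interaction. Noise in the simulation was drawn independently for each gene and array. In the real arrays genes vary together within groups, so these rates may not carry over to them.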

Results

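UVB vs control. Cyp24a1, which encodes the vitamin D 24-hydroxylase, rose by 7.26 ± 0.15 log2 units 24 h after UVB, a 153-fold change (adjusted p = 7.2e-11; n = 3 cultures per group). Genes of DNA synthesis followed: Exo1, an exonuclease, rose by 1.74 ± 0.17, Pclaf, a PCNA-associated factor, by 1.59 ± 0.10, and the origin licensing genes Orc1 and Cdc6 by 1.48 ± 0.16 and 1.41 ± 0.12. The monocyte chemoattractant Ccl2 rose by 1.78 ± 0.35 (adjusted p = 0.0123), while Krt2, a keratin of the upper layers, fell by 1.59 ± 0.32 (adjusted p = 0.0142) and Aadac, an arylacetamide deacetylase, was undetected after UVB. In all, 542 of 10937 genes passed, 325 higher and 217 lower; 86 of them changed at least 2-fold, 69 upward and 17 downward. The count was 360 without control A, 315 without control B, 335 without UVB B and 315 without UVB C, and 830 in an array-weighted model. With the authors' processed values Cyp24a1 rose by 5.13, and Krt2 (−0.45, adjusted p = 0.22) and Ccl2 (0.75, adjusted p = 0.059) had no call. With arrays scaled by their medians the split was 230 higher and 486 lower, so the share of higher genes moved from 60.0 to 32.1 percent.

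Other large rises after UVB were Serpina9 (1.67 ± 0.31), a serpin, Mis18a (1.47 ± 0.15), which acts at centromeres, Upb1 (1.45 ± 0.18), of pyrimidine breakdown, Atp2a3 (1.44 ± 0.17), a calcium pump of the endoplasmic reticulum, and Asf1b (1.40 ± 0.11), a histone chaperone. Among the falls, Aadac (−1.94 ± 0.27), Cdk14 (−1.85 ± 0.16), a cyclin-dependent kinase, and Bbs9 (−1.65 ± 0.18), of the cilium, were undetected in every UVB culture, so their falls are at least 2.29-fold, 3.10-fold and 2.15-fold. Pcp4, a calmodulin-binding protein, fell by 1.59 ± 0.12. Prkg1, the cGMP-dependent kinase, fell by 1.56 ± 0.18, with a change of −0.23 at its other probe, and the carboxylesterase Ces1d fell by 1.54 ± 0.28. The BMP antagonist Nbl1 fell by 1.21 ± 0.15, Sectm1a by 1.18 ± 0.16, the glycogen branching enzyme Gbe1 by 1.11 ± 0.15, Slit3 by 1.10 ± 0.21 and Bcas3 by 1.07 ± 0.19. Krt2, Prkg1, Ces1d and Bcas3 were detected in 2 of the 3 UVB cultures. Krt2 lost its call without control B (adjusted p = 0.069) or UVB C (0.064), and Slit3 without UVB C (0.051). Of all genes, 22.9 percent had arrays that do not overlap between these groups, against 10 percent by chance. With the authors' processed values the changes of dim genes were smaller, as for Aadac (−0.49), Cdk14 (−0.47), Prkg1 (−0.42), Exo1 (0.58) and Orc1 (0.60).

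DNA replication genes rose as a group after UVB: 27 of 30 measured members rose and 0 fell, with 30 higher when adjusted over the list alone, a median of 0.88 log2 and an adjusted p of 1.5e-45 (1.67e-04 with an estimated correlation). Members include Mcm3 (1.19 ± 0.11) of the replicative helicase, Rrm2 (1.14 ± 0.10), which supplies deoxynucleotides, and Pola2 (0.90 ± 0.08) of the primase complex. Among mitosis genes 10 of 29 rose and 0 fell (20 higher and 1 lower adjusted over the list alone; median 0.46; adjusted p = 1.0e-15, and 0.0603 with an estimated correlation); Cdk1 rose by 0.99 ± 0.11, Mad2l1 by 0.91 ± 0.11, Nuf2 by 0.87 ± 0.11 and Ccna2 by 0.79 ± 0.11. Of 23 nucleotide excision repair genes, Lig1 (0.72 ± 0.09) and Rpa2 (0.68 ± 0.10) rose, both also used in replication, with 2 higher and 1 lower adjusted over the list alone and a list adjusted p of 0.34. No p53 target of 18 passed in limma, while 3 had an unadjusted p under 0.05 and 0 passed adjusted over the list alone (list adjusted p = 0.925). Values for that list were Tp53inp1 0.36 ± 0.12 (adjusted p = 0.12), Sesn1 −0.27 (0.12), Mdm2 0.04 ± 0.09 and Cdkn1a, the p21 gene, 0.04 ± 0.31 (0.968).

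One-carbon and serine genes also rose after UVB: 6 of 17 rose and 0 fell (9 higher adjusted over the list alone; median 0.27; adjusted p = 8.5e-06, and 0.0332 with an estimated correlation). Psph (0.78 ± 0.13) and Phgdh (0.49 ± 0.11) make serine, Cth (0.68 ± 0.13) makes cysteine and Nnmt (0.43 ± 0.10) methylates nicotinamide. Of 23 heat shock and unfolded protein response genes 3 rose, Chac1 (0.93 ± 0.18), Asns (0.79 ± 0.14) and Trib3 (0.56 ± 0.14), with 6 higher adjusted over the list alone (list adjusted p = 3.3e-04, and 0.194 with an estimated correlation). Inflammatory mediators gave 4 rises in 20: Ccl2, Il1a (1.36 ± 0.29), the chemokine Cxcl10 (1.12 ± 0.17; undetected in control, at least 1.55-fold) and the prostaglandin E synthase Ptges (0.59 ± 0.14), with 6 adjusted over the list alone (median 0.33; adjusted p = 3.0e-05, and 0.187 with an estimated correlation). Among 22 EGF ligands and immediate early genes Fos (1.24 ± 0.23), Ier3 (0.76 ± 0.16) and Myc (0.36 ± 0.09) rose and the phosphatase Dusp1 (−0.38 ± 0.09) fell, 6 higher and 2 lower adjusted over the list alone (list adjusted p = 0.00275, and 0.187 with an estimated correlation). Interferon-stimulated genes had 0 of 17 past the threshold in limma and 6 with an unadjusted p under 0.05 (list adjusted p = 0.51). Trib3, Il1a, Ptges, Ier3, Myc, Dusp1, Cth, Nnmt and Phgdh each lost the call with at least 1 array left out, with adjusted p up to 0.139 (Myc).

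Keratinocyte layer genes moved in single members after UVB. In the late differentiation list Krt2 fell and the protease Klk6 rose by 0.59 ± 0.13, 1 each way of 29 measured (1 higher and 1 lower adjusted over the list alone; list median 0.10, adjusted p = 0.0449, and 0.697 with an estimated correlation). In the basal layer list Krt15 (−0.74 ± 0.14) and the integrin Itga2 (−0.60 ± 0.12) fell, 2 of 19, with 3 lower adjusted over the list alone (median −0.17; adjusted p = 0.0033, and 0.244 with an estimated correlation). The wound keratin Krt16 rose by 1.28 ± 0.28, 1 of 4 measured in its list, while Krt17 had 0.46 ± 0.23 without a call. Ebp (−0.34) and Hmgcs1 (−0.40) of cholesterol synthesis fell, 2 of 21 and 2 adjusted over the list alone (list adjusted p = 0.0158, and 0.429 with an estimated correlation). The aldose reductase Akr1b1, which makes the osmolyte sorbitol, rose by 0.69 ± 0.12 and the choline dehydrogenase Chdh, which feeds betaine synthesis, fell by 0.58 ± 0.10 among 21 osmolyte genes (1 higher and 2 lower adjusted over the list alone; list adjusted p = 0.70); the inositol transporter Slc5a3 had −0.73 ± 0.20 (adjusted p = 0.058) and Bhmt, which uses betaine to remethylate homocysteine, 0.08 ± 0.14 (0.82). Slc6a12, the betaine transporter, was undetected on every array. Krt16, Klk6, Itga2, Ebp and Hmgcs1 lost their calls with at least 1 array left out, with adjusted p up to 0.144 (Hmgcs1), and the late differentiation list lost its call without 3 of the 6 arrays, with adjusted p up to 0.926 (control A), as did the cholesterol list, up to 0.135 (control C).

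Among 28 NRF2 and antioxidant genes the glutathione synthesis gene Gclc (0.50 ± 0.08) and the metallothionein Mt1 (0.89 ± 0.17) rose after UVB. Adjusted over the list alone 2 were higher and 1 lower (list adjusted p = 0.22). In a model of the 2 groups alone 13 of the 60 calls named by rule in UVB vs control were lost, with adjusted p up to 0.125 (Myc). Among them were Mt1 (adjusted p = 0.056), Ccl2 (0.055), Il1a (0.063), Ier3 (0.076) and Ptges (0.106). Degs2, a ceramide hydroxylase, rose by 0.75 ± 0.19 among 20 barrier lipid genes (list adjusted p = 0.33). Mmp9 (−0.69) and Adamts1 (−0.67), both secreted proteases, fell among 19 protease and matrix genes, with Adamts1 undetected after UVB and lower by at least 1.28-fold, 3 lower adjusted over the list alone (list adjusted p = 0.44). Degs2, Mmp9 and Adamts1 lost their calls with at least 1 array left out, with adjusted p up to 0.148 (Adamts1). Hyaluronan genes had 0 of 10 past the threshold in limma, 2 with an unadjusted p under 0.05 and 1 higher adjusted over the list alone (list adjusted p = 0.70). Ribosomal proteins had 0 of 19 in limma and 0 with an unadjusted p under 0.05 (0.59).

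**Figure D1:**
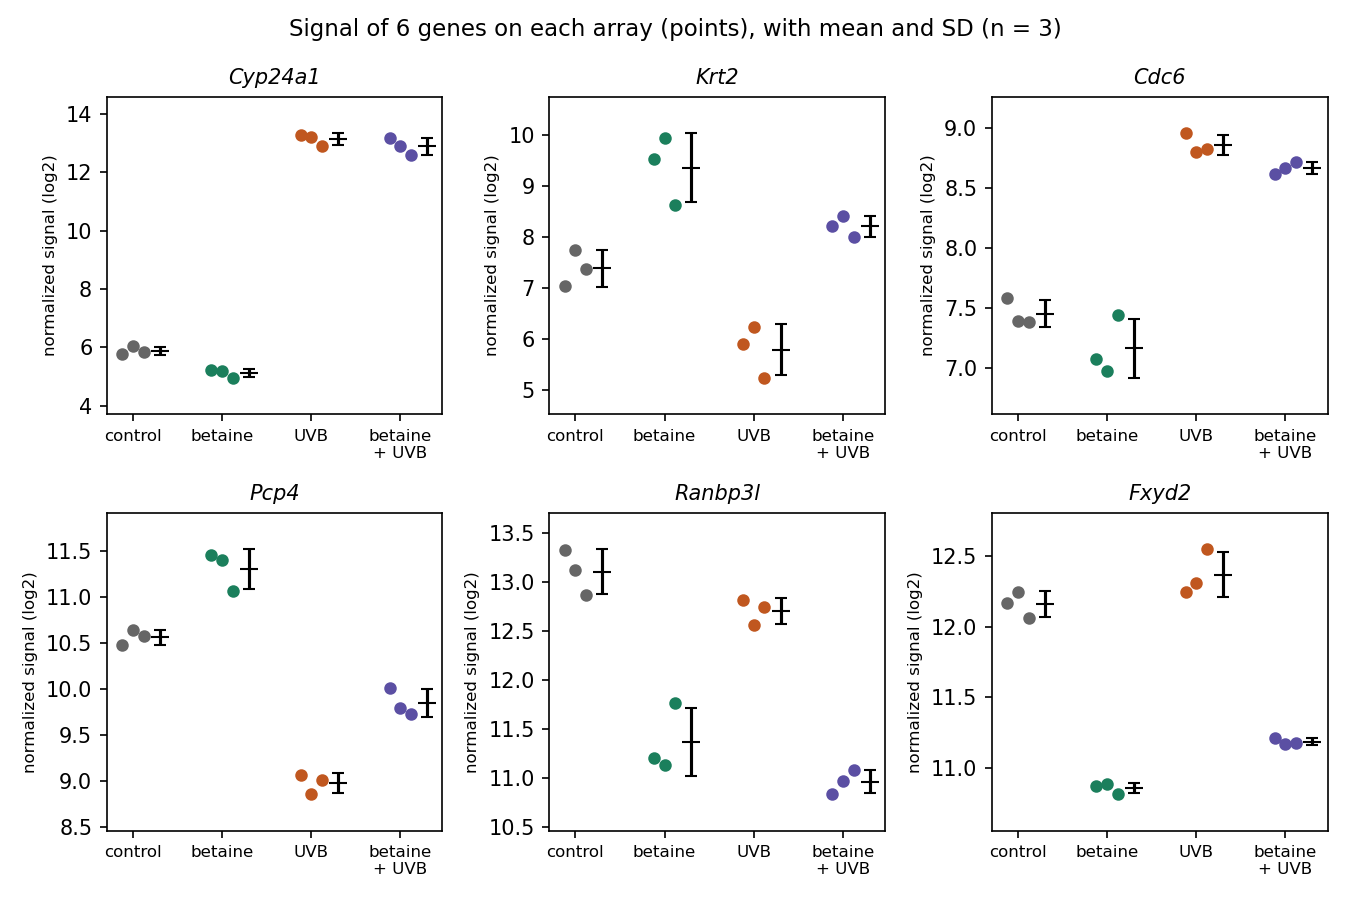
Normalized signal (log2) of Cyp24a1, Krt2, Cdc6, Pcp4, Ranbp3l and Fxyd2 in the 4 groups; points are arrays and bars are the mean ± SD of 3. Cyp24a1 is 5.88 in control and 13.14 after UVB, and Krt2 is 7.38 in control, 9.35 with betaine, 5.79 after UVB and 8.20 with both.

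Betaine vs control. Krt2 rose 3.93-fold with 11 days of betaine (1.98 ± 0.32 log2, adjusted p = 0.0193; n = 3 cultures per group), the largest rise of the comparison; with the authors' processed values it was 1.13 (adjusted p = 0.0202). Ranbp3l, related to a Ran-binding nuclear export factor, fell 3.34-fold (−1.74 ± 0.17, adjusted p = 0.0012), and Fxyd2, the gamma subunit of the sodium pump, fell 2.47-fold (−1.31 ± 0.09, adjusted p = 8.1e-05) with −1.38 at a second probe. The immediate early factor Egr1 (1.04 ± 0.11, adjusted p = 0.0017) and the chemokine Ccl5 (1.04 ± 0.10, adjusted p = 0.0012) rose. Of 10937 genes 98 passed, 40 higher and 58 lower, 19 of them at least 2-fold. The count was 16 without control A, 63 without control B, 24 without control C, 19 without betaine A and 16 without betaine B, and with an array of another group left out it was 57 without UVB A, 61 without UVB B, 63 without betaine + UVB A and 57 without betaine + UVB C. It was 430 in an array-weighted model, 34 without both control A and betaine C, 7 in a model of these 2 groups alone, and median scaling gave 21 higher and 109 lower, a share of 16.2 percent higher against 40.8.

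The other large rises with betaine were Nrp1 (1.11 ± 0.23), a semaphorin and VEGF co-receptor, undetected in control and at least 1.63-fold higher, Plet1 (1.09 ± 0.22), an epithelial surface protein, Cox8b (1.05 ± 0.11), a cytochrome oxidase subunit, Fmr1nb (1.01 ± 0.16) and the homeobox gene Dlx2 (0.96 ± 0.14). The protease inhibitor Serpina3n fell by 1.5 ± 0.22, the glutathione transferase Gsta4 by 1.07 ± 0.20 and the epithelial transcription factor Elf3 by 1.05 ± 0.13. Raet1l (−1.26 ± 0.21), an NKG2D ligand, Dapk1 (−1.26 ± 0.14), a death-associated kinase, and the peptide hormone gene Adm2 (−1.05 ± 0.16) were undetected with betaine, so their falls are at least 1.70-fold, 2.06-fold and 1.71-fold. Cyp24a1, also undetected with betaine, was lower by at least 1.21-fold (adjusted p = 0.0443). Ccl5 was detected in 1 of the 3 control cultures. Krt2 lost its call without control A (adjusted p = 0.089), control C (0.075), betaine A (0.073) or betaine B (0.069). With at least 1 array left out Nrp1, Plet1, Fmr1nb, Dlx2, Serpina3n, Gsta4, Raet1l and Adm2 also lost theirs, with adjusted p up to 0.166 (Plet1), while Ranbp3l, Fxyd2, Dapk1, Elf3, Egr1, Ccl5 and Cox8b kept them. In a model of the 2 groups alone 21 of the 27 calls named by rule were lost, with adjusted p up to 0.323 (Mcm7). Among them were Krt2 (adjusted p = 0.126), Egr1 (0.051), Serpina3n (0.104) and Dlx2 (0.120). With the authors' processed values 7 of the calls were lost, among them Adm2 (adjusted p = 0.091), Nrp1 (0.090), Raet1l (0.079), Plet1 (0.058) and Gsta4 (0.053). Serpina3n (−0.65), Elf3 (−0.35), Dapk1 (−0.28), Cox8b (0.30), Dlx2 (0.27) and Ccl5 (0.22) had smaller changes with those values. Arrays of the groups do not overlap in 14.5 percent of all genes, against 10 percent by chance.

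Cell cycle genes were lower with betaine as groups. In mitosis 1 of 29 fell, the cyclin Ccnb2 (−0.57 ± 0.11), and 21 were lower adjusted over the list alone (median −0.44; adjusted p = 6.8e-19, and 0.0352 with an estimated correlation); the kinesin Kif2c had −0.78 ± 0.16 (adjusted p = 0.052) and the proliferation marker Mki67 −0.57 ± 0.13 (0.067). In DNA replication 4 of 30 fell, the helicase subunits Mcm3 (−0.64 ± 0.11), Mcm4 (−0.50 ± 0.10) and Mcm7 (−0.49 ± 0.10) and Pola2 (−0.43 ± 0.08), and 14 were lower adjusted over the list alone (median −0.29; adjusted p = 1.3e-15, and 0.0086 with an estimated correlation). EGF ligands and immediate early genes were higher: Egr1, the AP-1 member Jun (0.58 ± 0.10) and the feedback inhibitor Spry2 (0.64 ± 0.13) rose, 3 of 22, with 7 adjusted over the list alone (median 0.24; adjusted p = 7.3e-08, and 0.0316 with an estimated correlation). Ccnb2, Mcm3, Mcm4, Mcm7, Pola2, Jun and Spry2 all lost their calls with at least 1 array left out, with adjusted p up to 0.195 (Mcm7).

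The osmolyte list held 1 fall in 21 with betaine, Akr1b1 (−0.76 ± 0.12), and 3 adjusted over the list alone (median −0.12; adjusted p = 0.0735). The heat shock protein gene Hspa4l had −0.61 ± 0.13 (adjusted p = 0.057), Slc5a3 −0.85 ± 0.20 (0.082) and Bhmt −0.03 ± 0.14 (0.964). Of 17 one-carbon genes the folate enzyme Mthfd1l (−0.61 ± 0.10) and Ahcy (−0.41 ± 0.08), which cleaves S-adenosylhomocysteine, fell, with 1 higher and 5 lower adjusted over the list alone (adjusted p = 8.1e-04, and 0.0618 with an estimated correlation); Psph had −0.62 ± 0.13 (0.057). Ccl5 was the 1 rise among 20 inflammatory mediators, 2 adjusted over the list alone (list adjusted p = 0.0082, and 0.362 with an estimated correlation), and the alarmin Il33 had 0.89 ± 0.22 (0.11). Krt2 was the 1 change among 29 late differentiation genes (list median 0.11, adjusted p = 0.0124, and 0.661 with an estimated correlation); without control A the list median was −0.04 and the adjusted p 0.877. The sterol carrier Stard4, undetected with betaine, was lower by at least 1.26-fold among 21 cholesterol genes (list adjusted p = 0.212), and Gsta4 was the 1 fall among 28 NRF2 genes. Akr1b1, Ahcy, Mthfd1l and Stard4 lost their calls with at least 1 array left out, with adjusted p up to 0.174 (Ahcy).

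Lists without a change in limma in betaine vs control were p53 targets (0 of 18; 1 with an unadjusted p under 0.05; list adjusted p = 0.853), among which Cdkn1a had 0.60 ± 0.31 (adjusted p = 0.502), and interferon-stimulated genes (0 of 17; 2 unadjusted; 0.853). The same held for basal layer (0 of 19; 5 unadjusted; 0.170), heat shock and unfolded protein response (0 of 23; 6 unadjusted; 0.868) and proteases (0 of 19; 6 unadjusted; 0.147). Barrier lipids had 0 of 20, with 0 unadjusted, and a list adjusted p of 0.567. Nucleotide excision repair had a list adjusted p of 0.212, hyaluronan 0.205 and ribosomal proteins 0.853.

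Betaine + UVB vs UVB. Krt2 again had the largest rise with betaine when every culture was irradiated, 5.34-fold (2.42 ± 0.32 log2, adjusted p = 0.0060; n = 3 cultures per group). With the authors' processed values Krt2 had 0.82 and no call (adjusted p = 0.066), and without background correction it rose by 1.60. Ranbp3l fell by 1.74 ± 0.17 and Fxyd2 by 1.18 ± 0.09 (adjusted p = 2.4e-04), close to their falls without UVB. Pcp4 (0.87 ± 0.12) and Nbl1 (0.88 ± 0.15), which fell with UVB alone, were higher with betaine, and Upb1, which rose with UVB alone, was lower (−1.32 ± 0.18). Both comparisons use the same cultures with UVB alone, which by itself favours opposite signs. Of 10937 genes 97 passed, 54 higher and 43 lower, 17 of them at least 2-fold. The count was 39 without UVB A, 31 without UVB B, 45 without UVB C, 59 without betaine + UVB A, 43 without B and 26 without C. It was 238 without betaine C, an array outside the comparison, 762 in an array-weighted model and 318 in a model of these 2 groups alone.

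Also higher were Dlx2 (0.93 ± 0.14), the troponin Tnnt2 (0.92 ± 0.15), Pappa (0.87 ± 0.16), a protease that frees IGF, Prss23 (0.85 ± 0.11), a serine protease, and the aldehyde dehydrogenase Aldh3a1 (0.85 ± 0.17). Lower were Serpina3n (−1.55 ± 0.22), the sorting nexin Snx10 (−1.45 ± 0.16), Raet1l (−1.44 ± 0.21), the cytochrome P450 Cyp2f4 (−1.35 ± 0.25) and Gsta4 (−1.27 ± 0.20). With the authors' processed values Snx10 (−0.67), Upb1 (−0.65), Serpina3n (−0.63) and Dlx2 (0.22) had smaller changes. Cyp24a1 had −0.24 ± 0.15 (adjusted p = 0.45). Dlx2, Tnnt2, Nbl1, Pappa, Aldh3a1, Raet1l, Cyp2f4 and Gsta4 lost their calls with at least 1 array left out, with adjusted p up to 0.179 (Aldh3a1). Arrays of the groups do not overlap in 28.6 percent of all genes, against 10 percent by chance.

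Gene lists in betaine + UVB vs UVB held few changed members. Ccne2 (−0.62 ± 0.13), the S-phase cyclin, was the 1 fall among 30 DNA replication genes, with 5 lower adjusted over the list alone (median −0.13; adjusted p = 3.2e-04, and 0.339 with an estimated correlation), and Mad2l1 (−0.70 ± 0.11) the 1 fall among 29 mitosis genes (list adjusted p = 0.286). Krt2 was the 1 rise among 29 late differentiation genes, whose median was −0.21 (adjusted p = 0.0051, and 0.573 with an estimated correlation). In the basal layer list 0 of 19 passed in limma and 4 were higher adjusted over the list alone (median 0.19; adjusted p = 0.0051, and 0.413 with an estimated correlation); Plec had 0.47 ± 0.11 (0.068) and Lama5 0.53 (0.092). Degs2 fell by 1.12 ± 0.19 among 20 barrier lipid genes (list adjusted p = 0.0051, and 0.554 with an estimated correlation). One-carbon genes had 0 of 17 (median −0.18; adjusted p = 0.0105, and 0.358 with an estimated correlation) and cholesterol genes 0 of 21, with 3 lower adjusted over the list alone (median −0.23; adjusted p = 0.0036, and 0.413 with an estimated correlation). Ccne2, Mad2l1 and Degs2 lost their calls with at least 1 array left out, with adjusted p up to 0.191 (Ccne2), and the late differentiation list with 2 arrays in turn, up to 0.0883 (UVB B).

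Akr1b1 (−0.86 ± 0.12) and Hspa4l (−0.86 ± 0.13) fell and Chdh (0.51 ± 0.10) rose among 21 osmolyte genes in the irradiated cultures, with 2 higher and 3 lower adjusted over the list alone (list adjusted p = 0.311); the kinase Sgk1 had −0.38 (0.072) and Bhmt −0.02 ± 0.14. Ccl5, undetected after UVB alone, was higher by at least 1.24-fold among inflammatory mediators (list adjusted p = 0.635), where Ccl2 had −1.0 ± 0.35 (0.20), and Egr1 rose by 0.64 ± 0.11 among immediate early genes (0.365). NRF2 genes held Aldh3a1 and Gsta4, 1 each way of 28 (0.458). In limma 0 of 18 p53 targets passed, with 2 at an unadjusted p under 0.05 (0.311), and Cdkn1a had −0.08 ± 0.31 (0.925). Proteases had 0 of 19, with 7 unadjusted and 5 higher adjusted over the list alone, heat shock and unfolded protein response 0 of 23 with 5 unadjusted, and hyaluronan 0 of 10 with 0 unadjusted. Hspa4l, Chdh, Ccl5 and Egr1 lost their calls with at least 1 array left out, with adjusted p up to 0.210 (Chdh).

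Betaine + UVB vs betaine. With betaine present, UVB again raised Cyp24a1 most, at least 157-fold (7.77 ± 0.15 log2, adjusted p = 3.2e-11, n = 3 cultures per group). The gene was undetected in every betaine culture, and this bound holds for the background correction used. With the authors' processed values the rise was 5.0 log2, and the cause of the difference was not tested. The replication licensing genes Cdt1 (1.94 ± 0.22) and Orc1 (1.92 ± 0.16), the helicase subunit Mcm3 (1.76 ± 0.11) and the polymerase Pole (1.73 ± 0.14) rose. Krt2 had −1.15 ± 0.32 without a call (adjusted p = 0.058), and it had a call without betaine C (−1.52, adjusted p = 0.0061), with the authors' processed values (−0.76, 0.0349), without background correction (0.0207), with normexp (0.0212), with a replicate block (0.0083) and with array weights (7.4e-04). Of 10937 genes 672 passed, 423 higher and 249 lower, 143 of them at least 2-fold. The count was 426 without betaine B, 426 without betaine + UVB A, 433 without B and 366 without C, and 2212 in an array-weighted model.

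Exo1 (1.88 ± 0.17), Pclaf (1.87 ± 0.10) and Asf1b (1.76 ± 0.11) also rose, with Exo1 detected in 2 of the 3 betaine cultures. Aadac fell by 2.13 ± 0.27, at least 2.65-fold since it was undetected with both treatments. Prkg1 (−1.99 ± 0.18) and Cdk14 (−1.77 ± 0.16) fell and were detected in 1 of the 3 irradiated cultures. The sodium pump subunit Atp1b1 fell by 1.79 ± 0.34, the cytokine Il36a by 1.57 ± 0.40, the stromelysin Mmp10 by 1.55 ± 0.30, the cytochrome P450 Cyp2b21 by 1.51 ± 0.38 and the glutathione transferase Gsta2 by 1.51 ± 0.32. Il36a, Cyp2b21 and Gsta2 lost their calls with at least 1 array left out, with adjusted p up to 0.164 (Il36a). With the authors' processed values Cdt1 (0.72), Orc1 (0.69), Exo1 (0.57), Aadac (−0.54) and Prkg1 (−0.55) had smaller changes. Arrays of the groups do not overlap in 27.3 percent of all genes, against 10 percent by chance.

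DNA replication and mitosis genes both rose with UVB in the betaine cultures. In replication 27 of 30 rose and 0 fell, 29 adjusted over the list alone, with Mcm6 at 1.35 ± 0.11, Cdc6 at 1.51 ± 0.12 and Rrm2 at 1.23 ± 0.10 (median 1.03; adjusted p = 3.5e-43, and 2.05e-04 with an estimated correlation). In mitosis 25 of 29 rose and 0 fell, 26 adjusted over the list alone, with Cdk1 at 1.25 ± 0.11, Ccna2 at 1.24 ± 0.11, Nuf2 at 1.08 ± 0.11 and Ndc80 at 0.95 ± 0.09 (median 0.90; adjusted p = 1.7e-28, and 0.0166 with an estimated correlation). One-carbon genes gave 7 rises in 17, 9 adjusted over the list alone, among them Psph (1.10 ± 0.13), Mthfd1l (0.81 ± 0.10), Phgdh (0.61 ± 0.11) and Ahcy (0.40 ± 0.08), with a median of 0.40 (adjusted p = 1.9e-05, and 0.0269 with an estimated correlation). Cholesterol genes gave 4 falls in 21, Mvd (−0.41), Fdps (−0.36), Tm7sf2 (−0.34) and Ebp (−0.32), with 1 higher and 10 lower adjusted over the list alone (median −0.30; adjusted p = 1.4e-04, and 0.317 with an estimated correlation). Sprr3, a cornified envelope precursor, fell by 1.5 ± 0.38, the 1 change among 29 late differentiation genes (list median −0.14; adjusted p = 0.0198, and 0.760 with an estimated correlation). Ahcy, Mvd, Fdps, Tm7sf2, Ebp and Sprr3 lost their calls with at least 1 array left out, with adjusted p up to 0.174 (Fdps), and the late differentiation list with 2 arrays in turn, up to 0.194 (betaine + UVB C).

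Stress genes with single changes in this comparison include Chac1 (1.27 ± 0.18), Asns (1.01 ± 0.14), Trib3 (0.81 ± 0.14) and Atf4 (0.44 ± 0.12), 4 rises in 23 and 6 adjusted over the list alone (list adjusted p = 0.173). Lig1 (0.91) and Rpa2 (0.88) rose while the repair gene Xpa (−0.46) fell, and Sesn1 (−0.41 ± 0.09) was the 1 change among 18 p53 targets, where Cdkn1a had −0.64 ± 0.31 (0.27). Itga2 fell by 0.98 ± 0.12 while the integrins Itgb4 (0.46) and Itga3 (0.73) rose among 19 basal layer genes (0.339). Cxcl10, undetected with betaine alone, was higher by at least 1.44-fold and Ccl5 fell by 0.62 ± 0.10 among 20 inflammatory mediators (0.366). Gclc (0.68 ± 0.08), Mt1 (1.02 ± 0.17), Akr1b1 (0.58 ± 0.12), Myc (0.42), Mmp2 (0.46), Mmp3 (0.66) and the hyaluronan receptor Hmmr (0.73 ± 0.11) rose, and Dusp1 (−0.37), Pemt (−0.46) and the sphingomyelinase Smpd1 (−0.40) fell; Bhmt had 0.09 ± 0.14. In limma 0 of 17 interferon-stimulated genes passed, with 3 at an unadjusted p under 0.05. Atf4, Sesn1, Itgb4, Itga3, Myc, Mmp2, Mmp3, Dusp1, Pemt and Smpd1 lost their calls with at least 1 array left out, with adjusted p up to 0.184 (Pemt).

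**Figure D2:**
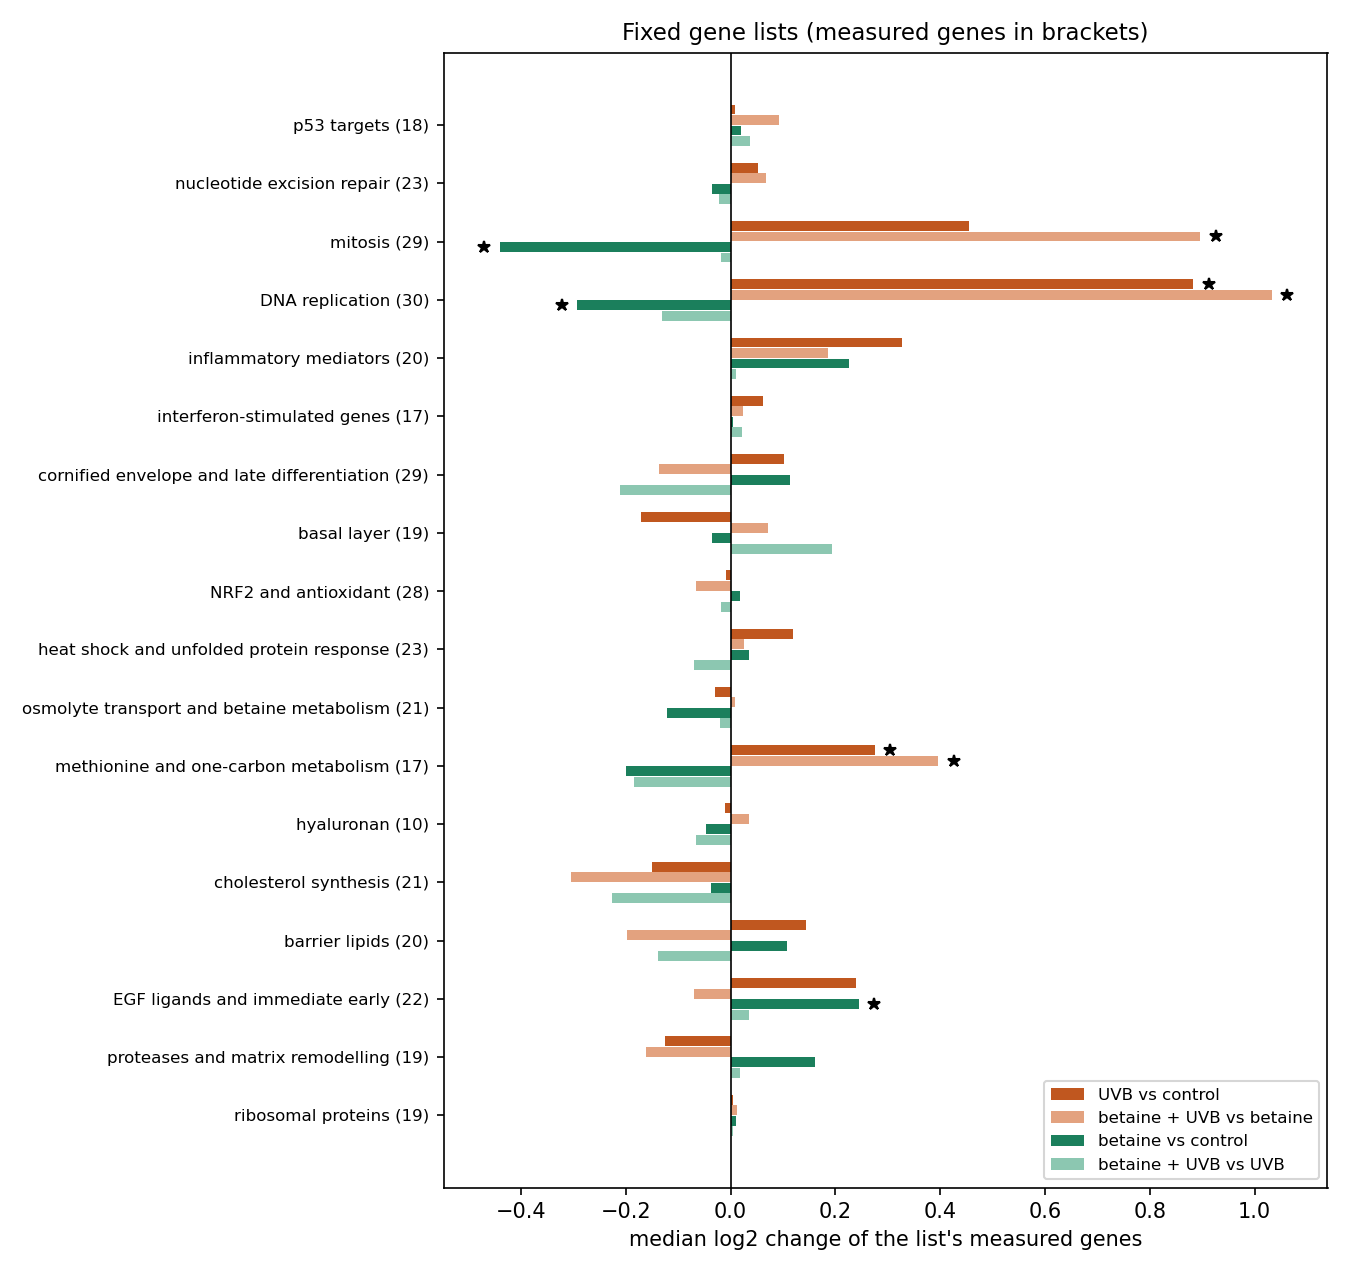
Median log2 change of 18 gene lists in 4 comparisons of 2 groups; a star marks an adjusted camera p under 0.05 with both the preset and the estimated correlation. DNA replication is 0.88 in UVB vs control, −0.29 in betaine vs control and 1.03 in betaine + UVB vs betaine.

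Betaine + UVB vs control. The 2 treatments together changed 565 of 10937 genes, 327 higher and 238 lower, 90 of them at least 2-fold (n = 3 cultures per group). DNA replication genes rose in 25 of 30 members (median 0.68; adjusted p = 3.8e-31, and 6.95e-04 with an estimated correlation), led by Pole (1.47 ± 0.14). Mitosis genes rose in 10 of 29 (median 0.44; adjusted p = 1.7e-11, and 0.152 with an estimated correlation). Cholesterol genes fell in 7 of 21 (median −0.28; adjusted p = 3.3e-07, and 0.152 with an estimated correlation), and immediate early genes gave 5 rises and 1 fall in 22 (adjusted p = 0.0013, and 0.152 with an estimated correlation), with Egr1 at 0.97 ± 0.11. Slc5a3 fell by 1.29 ± 0.20 (adjusted p = 0.0025), and Krt2 had 0.83 ± 0.32 (0.177). The count was 355 without control B, 356 without control C, 317 without betaine + UVB A, 374 without B and 325 without C, 905 without betaine C, an array outside the comparison, and 1562 in an array-weighted model. Median scaling gave 246 higher and 378 lower, a share of 39.4 percent higher against 57.9.

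UVB averaged over the betaine states. Cyp24a1, undetected in the betaine cultures, rose at least 155-fold (adjusted p = 8.0e-13; n = 6 irradiated and 6 mock cultures); with the authors' processed values the rise was 5.06 log2. Exo1 (1.81 ± 0.12), Pclaf (1.73 ± 0.07), Orc1 (1.70 ± 0.11), Cdt1 (1.63 ± 0.15), Asf1b (1.58 ± 0.08) and the kinetochore gene Kntc1 (1.52 ± 0.11) rose. Aadac (−2.03 ± 0.19), Cdk14 (−1.81 ± 0.12), Prkg1 (−1.77 ± 0.13), Pcp4 (−1.52 ± 0.08), Ces1d (−1.46 ± 0.20), Krt2 (−1.37 ± 0.23), Bbs9 (−1.31 ± 0.12) and Mmp10 (−1.29 ± 0.21) fell, and all of these genes kept their calls with each array left out. Aadac was undetected in all 6 irradiated cultures and Cdk14 and Bbs9 in those without betaine, so their falls are at least 2.46-fold, 3.25-fold and 2.06-fold; with the authors' processed values Aadac had −0.52. Of 10937 genes 1229 passed, 665 higher and 564 lower, 103 at least 2-fold, and 2383 in an array-weighted model; median scaling gave 524 higher and 882 lower, a share of 37.3 percent higher against 54.1. DNA replication genes rose in 29 of 30 members (median 0.93; adjusted p = 4.3e-46, and 1.6e-04 with an estimated correlation), mitosis genes in 24 of 29 (median 0.71; adjusted p = 1.3e-25, and 0.0153 with an estimated correlation) and one-carbon genes in 10 of 17 (median 0.30; adjusted p = 1.3e-06, and 0.0153 with an estimated correlation). Cholesterol genes fell in 8 of 21 (median −0.22; adjusted p = 2.8e-04, and 0.360 with an estimated correlation). The simple epithelial keratin Krt7 rose by 0.52 ± 0.13, a call lost with 2 arrays left out in turn, with adjusted p up to 0.0530 (control C).

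Betaine averaged over the UVB states. Krt2 rose 4.58-fold (2.20 ± 0.23 log2, adjusted p = 3.2e-04; n = 6 cultures with and 6 without betaine), and by 0.97 log2 with the authors' processed values (adjusted p = 0.0032). Ranbp3l fell 3.34-fold (−1.74 ± 0.12) and Fxyd2 2.37-fold (−1.24 ± 0.06, adjusted p = 2.7e-06), followed by Serpina3n (−1.52 ± 0.15), Raet1l (−1.35 ± 0.15), Gsta4 (−1.17 ± 0.14), Snx10 (−1.16 ± 0.11), Dapk1 (−1.06 ± 0.10) and Cyp2f4 (−1.01 ± 0.18). The matricellular gene Ccn2 (1.18 ± 0.22), Prl8a7 (1.10 ± 0.26), Dlx2 (0.94 ± 0.10), Ces1d (0.92 ± 0.20), Tmem121b (0.85 ± 0.18), Ccl5 (0.85 ± 0.07) and Egr1 (0.84 ± 0.08) rose. Raet1l and Dapk1 were undetected with betaine alone, and Ccn2 and Ccl5 after UVB alone, so these changes are at least 2.15-fold, 1.93-fold, 1.93-fold and 1.60-fold. Of 10937 genes 355 passed, 182 higher and 173 lower, 13 at least 2-fold. The count was 200 without control C, 235 without betaine A, 232 without UVB A, 210 without UVB B, 227 without UVB C, 222 without betaine + UVB A, 180 without B and 179 without C, and 1272 in an array-weighted model. Prl8a7, Ces1d and Tmem121b lost their calls with at least 1 array left out, with adjusted p up to 0.113 (Prl8a7).

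With the UVB states averaged, Akr1b1 fell with betaine by 0.81 ± 0.08, Hspa4l by 0.73 ± 0.09, Slc5a3 by 0.70 ± 0.14 and Sgk1 by 0.31 ± 0.06, while Chdh (0.35 ± 0.07) and the choline transporter Slc44a1 (0.30 ± 0.07) rose. The osmolyte list, with 2 rises and 4 falls in 21, had no call (adjusted p = 0.164, and 0.437 with an estimated correlation). DNA replication genes fell in 6 of 30 members and 16 adjusted over the list alone (median −0.24; adjusted p = 7.6e-13, and 0.0152 with an estimated correlation). Mitosis genes fell in 4 of 29 and 14 adjusted over the list alone (median −0.26; adjusted p = 4.9e-10, and 0.132 with an estimated correlation). Immediate early genes rose in 4 of 22 and 8 adjusted over the list alone (median 0.14; adjusted p = 3.9e-04, and 0.132 with an estimated correlation). One-carbon genes fell in 3 of 17 (median −0.15; adjusted p = 3.9e-04, and 0.0957 with an estimated correlation), and Cyp51 (−0.45) and Stard4, undetected with betaine alone and lower by at least 1.36-fold, fell among 21 cholesterol genes (list adjusted p = 0.0064, and 0.403 with an estimated correlation). The metalloproteases Mmp3 (0.74), Mmp9 (0.52) and Mmp28 (0.36) and the alarmin Il33 (0.74 ± 0.16) rose. Cyp24a1, undetected with betaine alone, was lower by at least 1.20-fold (adjusted p = 0.0284), with no call among irradiated cultures. Slc5a3, Sgk1, Cyp51, Mmp9, Mmp28 and Il33 lost their calls with at least 1 array left out, with adjusted p up to 0.112 (Cyp51).

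Interaction of UVB and betaine. No gene passed in limma, with 880 of 10937 at an unadjusted p under 0.05 and a lowest adjusted p of 0.4288. The lowest p-values with a positive interaction, that is a UVB change (log2) more positive with betaine than without it, were those of Tbc1d25 (0.69 ± 0.12), the enolase Eno3 (0.88 ± 0.16), the arginine transporter Slc7a1 (0.83 ± 0.15), Zfp775 (0.82 ± 0.16) and Sytl2 (0.63 ± 0.12), and with a negative interaction Krt36 (−0.84 ± 0.16), Vopp1 (−0.62 ± 0.13), the phosphatase inhibitor Ppp1r2 (−1.06 ± 0.22), Cox8b (−0.67 ± 0.15) and the adrenomedullin gene Adm (−0.77 ± 0.17), all at an adjusted p of 0.4288 or 0.5572. Krt2 had 0.44 ± 0.45 (0.834), Cyp24a1 0.52 ± 0.21 (0.60), Cdkn1a −0.68 ± 0.44 and Bhmt 0.01 ± 0.19. Cyp24a1 was undetected in every culture with betaine alone, and Cox8b in every culture with UVB alone. Both interactions therefore include a group at background and are not exact. The UVB rise of Cyp24a1 was at least 157-fold with betaine, against 153-fold without it. The interleukin 1 genes Il1a (−1.31 ± 0.41) and Il1rn (−1.25 ± 0.36) and the cell cycle genes Ccnb2 (0.53 ± 0.16) and Mcm3 (0.57 ± 0.16) had no call. An array-weighted model gave 10 genes.

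Of the lists, 7 passed in the interaction with the preset correlation and 0 with the estimated correlation. Mitosis had a median of 0.43 (adjusted p = 9.6e-10, and 0.192 with an estimated correlation), basal layer 0.31 (6.3e-05, and 0.192 with an estimated correlation) and DNA replication 0.12 (0.0051, and 0.302 with an estimated correlation). Late differentiation had −0.33 (3.4e-06, and 0.411 with an estimated correlation), immediate early genes −0.26 (1.5e-04, and 0.192 with an estimated correlation), barrier lipids −0.28 (7.3e-04, and 0.411 with an estimated correlation) and inflammatory mediators −0.23 (0.0017, and 0.411 with an estimated correlation). Leaving out UVB C took the inflammatory list to an adjusted p of 0.246.

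UVB-responsive genes in the interaction. The 665 genes raised by UVB averaged, such as Mcm3 and Cdc6, had a median UVB change of 0.45 without and 0.53 with betaine and a median interaction of 0.10 (camera p = 2.0e-05, and 0.151 with an estimated correlation). In 31.4 percent of them, 209 genes, the interaction was negative, that is the UVB change was lower with betaine than without it. The 564 lowered genes, such as Pcp4, had a median interaction of 0.01 (p = 0.782, and 0.863 with an estimated correlation), which was positive, against the fall, in 52.3 percent, 295 genes. The change with betaine itself is another measure: averaged over the UVB states it had a median of −0.11 in the raised genes, and it had the same sign as the UVB change in 175 of the raised (26.3 percent) and 220 of the lowered genes (39.0 percent).

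UVB and betaine effects across genes. Genes called for both averaged effects mostly moved in opposite directions: 72 rose with UVB and fell with betaine, against 10.5 expected by chance, among them Adm2 (1.10 ± 0.12 and −0.83 ± 0.12), Psph (0.94 ± 0.09 and −0.46 ± 0.09) and Asns (0.90 ± 0.10 and −0.46 ± 0.10); the betaine calls of Psph and Asns were lost with at least 1 array left out, with adjusted p up to 0.0689 and 0.0649. Adm2 was undetected in every culture with betaine alone, so both its sizes include a group at background and are not exact. Another 63 genes fell with UVB and rose with betaine, against 9.39, among them Krt2 and Ces1d. In the same direction 8 rose, against 11.1, and 18 fell, against 8.92, among them Slc5a3. Across 10937 genes, which are not independent, the averaged effects had a correlation of −0.198. The opposite direction is not set apart from relabelled groups: with betaine relabelled, 20 of 100 labellings were as one-sided as the real 83.9 percent. The UVB effects with and without betaine, which share no arrays, had 0.573, with 240 genes such as Cdc6 higher in both (12.6 by chance), 101 such as Cdk14 lower in both (4.94) and 0 opposite. The betaine effects with and without UVB had 0.326, with 21 genes such as Krt2 and Dlx2 higher in both (0.197 by chance), 18 such as Ranbp3l and Fxyd2 lower in both (0.228) and 0 opposite. The chance counts in this paragraph treat genes and calls as independent. All comparisons share 1 estimate of the spread per gene, and genes vary together, so these counts can be too low.

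**Figure D3:**
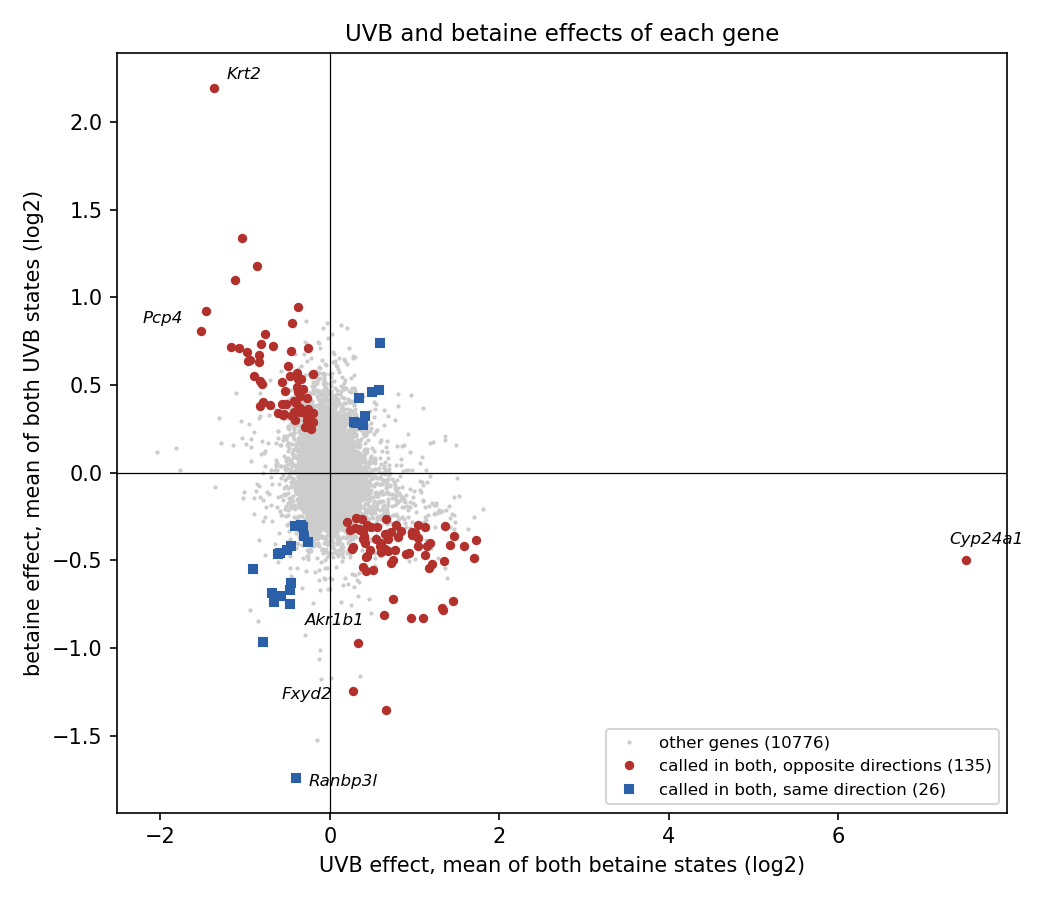
Change with UVB averaged over the betaine states (log2, horizontal) against change with betaine averaged over the UVB states (log2, vertical); each point is 1 of 10937 genes. Colours mark 135 genes called for both with opposite signs and 26 called with the same sign.

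Arrays and markers. The 2 cultures of a group correlated at 0.987 to 0.997 over the tested genes, and the lowest value for any 2 arrays was 0.980. The main axis of variation, 31.9 percent, separates irradiated from mock cultures; the next holds 24.8 percent. Of 15 measured markers of other cell types in 5 lists, Krt7 was the only 1 with a call, in UVB averaged and in betaine + UVB vs control (0.93 ± 0.18, adjusted p = 0.0106, and 0.0522 without betaine + UVB C). In limma 0 of the markers passed in UVB vs control, with 2 at an unadjusted p under 0.05, and 0 in betaine vs control, with 3. Control A and betaine C had the highest scores on the leading axis of within-group differences, 0.44 and 0.58, and betaine B the lowest, −0.445; the late differentiation genes of control A stood at a median of −0.32 against the mean of their group. Without those 2 arrays, a choice made after seeing the data, the counts were 34 in betaine vs control, 561 in betaine + UVB vs UVB, 1218 in betaine + UVB vs betaine and 1321 in betaine + UVB vs control. Over all comparisons 50 list tests passed with the preset correlation and 13 with the estimated correlation.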

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

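In this part, the splits and relabellings of the counts and of the UVB-raised genes were fixed before their results were seen, and all other tests, with the relabelling of the direction of change, were chosen after the result they address. A probe without a gene name, outside the main measurement, was 0.4295 log2 higher in betaine + UVB vs control (adjusted p = 0.0209); of 117 probes without a name, 5 were detected on at least 3 arrays.

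Splits of 6 arrays into 3 and 3 number only 10, too few to judge a count: the real split ranked 1 in UVB vs control (542 genes; highest other 0), betaine vs control (98; 0), betaine + UVB vs UVB (97; 0), betaine + UVB vs betaine (672; 0) and betaine + UVB vs control (565; 0). Of 100 relabellings of the 12 arrays, 1, the real one, reached the count in UVB averaged (1229; highest other 0) and in betaine averaged (355; highest other 3). For the interaction, with 0 genes, 100 of 100 did as well, and 1 relabelling gave 876 genes. That relabelling set control A, betaine A and betaine C against control B, control C and betaine B. The irradiated arrays kept their true labels in it, so its count also holds the real betaine effect among irradiated cultures. The same split of the unirradiated arrays gave 0 genes in betaine vs control, so the 876 do not rest on those arrays alone. The next highest relabelling gave 355 genes, the same count as betaine averaged. With betaine labels swapped among irradiated cultures only, the interaction contrast becomes the averaged betaine effect. That count can therefore be the real betaine effect. Of the 100 labellings, 5 gave any gene. The median interaction of the UVB-raised genes, 0.1047, was reached in 25 of 100 (highest other 0.2218). Relabelled groups can hold the real betaine effect, whose averaged median in these genes was −0.1109. The relabelling therefore cannot decide if this interaction is larger than chance gives.

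Genes moved in opposite directions with UVB and betaine, 135 of the 161 called for both, among them Krt2, Psph and Asns. With betaine relabelled, the genes ranked highest were as one-sided as the real 83.9 percent in 20 of 100 labellings (17.4 to 93.8 percent), and the correlation across genes, −0.198, was matched in size by 17 of 100 (range −0.269 to 0.175) and was −0.053 without control A, so the grouping of these arrays could give this direction by itself. Control A alone does not account for the number of opposite calls, since without that array 101 stand against 18.2 by chance, a ratio of 5.56 (6.78 with all arrays). That chance count treats genes as independent, unlike the relabelling, so the ratio does not set chance aside. The 2 leading components of the differences between arrays of a group hold 37.9 and 18.3 percent of that variation. They do not account for the correlation, which stays at −0.267 after regression on them (−0.314 to −0.165 with 1 array left out). The remaining components were not removed, so differences within groups are not excluded as a cause. A treatment effect of betaine counter to that of UVB is a biological explanation that these values leave open.

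DNA replication genes such as Mcm3 and Cdc6 were higher after UVB, with a median of 0.93 ± 0.08 in UVB averaged over 30 genes. A larger share of basal cells could give this, but the 19 basal layer genes had a median of −0.0407 ± 0.08. Members of that list moved both ways with UVB, so their median is only an indirect measure of the basal share. Scaling between arrays could also give it, but over the scalings the median of the replication list itself stayed at 0.6533 to 0.9608. Its lowest difference from the median of all genes was 0.6603, with the authors' processed values. A shift of whole arrays cancels in that difference, so it bears only on scalings that act unevenly across genes. More cells in, or held in, S phase 24 h after UVB remains a possible explanation that RNA levels alone do not test.

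Cyp24a1 rose at least 155-fold with UVB averaged, and by 5.06 log2 with the authors' processed values. It is a known target of the vitamin D receptor, and UVB makes previtamin D in skin, so a rise of other receptor targets was tested. The 9 measured targets had a median of 0.0332 ± 0.119 (p = 0.223 with an estimated correlation), and 2 rose, Klk6 (0.47) and Thbd (0.44). These 9 targets as a set thus showed no rise on the scale of Cyp24a1. So few genes, of which 2 rose, cannot exclude a smaller or partial response of receptor targets. A response of Cyp24a1 alone to the receptor could still be the cause and was not tested. Its highest group mean, 13.14 log2, lies below the brightest probes of the array.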

How the results depend on the processing

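The choice to leave out control A and betaine C together was made after the data were seen; all other alternatives were fixed before. The counts stayed within 1.5 times under the other background corrections, cyclic loess, median scaling, the authors' processed values, both filters, every probe on its own, the intensity trend and the replicate block. Of the 50 called lists 47 to 50 kept their calls under these settings, except every probe on its own and the intensity trend, which were not run on lists. The replicate block gave 440, 77, 80, 631, 539, 0, 1109 and 307 genes in the order below. The replicate letters do not pair cultures throughout: 18 same-letter pairs correlated at −0.384 to 0.340, with a median of 0.001. The median for pairs with different letters was −0.013. Of the same-letter pairs 8 lay over 0.1, so a batch that follows some of the letters is not excluded. A block for the slide was not run, as the files give no slide. Signal near background and 3 arrays per group limit what falls in dim genes can show.

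In the order UVB vs control, betaine vs control, betaine + UVB vs UVB, betaine + UVB vs betaine, betaine + UVB vs control, interaction, UVB averaged and betaine averaged, array weights gave 830, 430, 762, 2212, 1562, 10, 2383 and 1272 genes; the cause was not tested. Adjusted p under 0.01 gave 246, 11, 24, 314 and 264 for the comparisons of 2 groups and 671 and 89 for the averaged effects. A fold of at least 1.5 gave 312, 59, 385 (betaine + UVB vs betaine), 329 (betaine + UVB vs control), 361 and 82; both follow from the narrower rule. Only the groups compared gave 7 in betaine vs control and 318 in betaine + UVB vs UVB. Without control A and betaine C the counts were 34, 561, 1218 and 1321 in the comparisons of 2 groups that moved; the cause was not tested. With an estimated correlation 13 of the 50 lists kept their calls, and the UVB-raised genes (31.43 percent with an interaction against the UVB change) had p = 0.151.

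With 1 array of the groups compared left out, counts ran over 315 to 390, 16 to 69, 26 to 59, 366 to 919, 317 to 661, 0 to 0, 908 to 1516 and 179 to 421, list calls over 48 to 54, shares with an interaction against the UVB change over 25.18 to 38.13 percent of raised and 39.74 to 60.24 percent of lowered genes, and correlations over −0.2483 to −0.0528 (UVB with betaine), 0.1113 to 0.5176 (betaine effects) and 0.4677 to 0.6883 (UVB effects); the cause was not tested. With an array outside the groups compared left out the count reached 709 in UVB vs control, 238 in betaine + UVB vs UVB and 905 in betaine + UVB vs control, each without betaine C, and fell to 57 in betaine vs control. For the UVB-lowered genes (52.3 percent with an interaction against the UVB change) the direction of the list test, which had no call, turned with median scaling (70.07 percent), with no filter (53.19) and with 6 of the 12 arrays left out in turn (52.9 to 60.24), while the test passed without betaine C (39.74); the cause was not tested.

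Uncalled values that turned sign, cause not tested, were Krt2 in the interaction (−0.0391 without background correction, −0.0274 with normexp, −0.3067 with the authors' values), and Cdkn1a (−0.055) and Mdm2 (−0.0897) in UVB vs control with median scaling. With 1 array left out Bhmt ran over −0.1901 to 0.1032 in betaine vs control, −0.0857 to 0.0474 in betaine + UVB vs UVB, −0.0399 to 0.2534 in betaine + UVB vs betaine, −0.1226 to 0.1707 in the interaction and −0.1048 to 0.0419 in betaine averaged, Cdkn1a over −0.0848 to 0.0987 in UVB vs control and −0.243 to 0.0503 in betaine + UVB vs UVB. The late differentiation list, called in betaine vs control with all arrays, ran over −0.0411 to 0.1901 and turned sign without control A. Krt2, called in the main model, had −0.45 (adjusted p = 0.22) in UVB vs control and 0.82 (0.066) in betaine + UVB vs UVB with the authors' values. In betaine + UVB vs betaine, where Krt2 had no call, it had one with the authors' values (−0.7555, adjusted p = 0.03487), without background correction (0.02074), with normexp (0.02116), the replicate block (0.008285), array weights (7.355e-04) and without betaine C (−1.5199, adjusted p = 0.006091); the cause was not tested.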

Other observations

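Every test in this part was chosen after the result that led to it was seen. Genes of the amino acid response, which cells raise when amino acids run short, were higher after UVB and several were lower with betaine (UVB averaged, then betaine averaged; log2, n = 6 against 6). Pck2, the mitochondrial PEP carboxykinase, had 1.35 ± 0.08 and −0.50 ± 0.08, the glutamine transporter Slc1a5 1.12 ± 0.10 and −0.47 ± 0.10, Adm2 1.10 ± 0.12 and −0.83 ± 0.12, the serine gene Psph 0.94 ± 0.09 and −0.46 ± 0.09, the asparagine synthetase Asns 0.90 ± 0.10 and −0.46 ± 0.10, and the proline synthesis gene Aldh18a1 0.84 ± 0.07 and −0.33 ± 0.07. All 12 of these values passed in limma with every array. Since Adm2 was undetected in every culture with betaine alone, both its sizes include a group at background and are not exact. With at least 1 array left out the betaine calls of Slc1a5 (adjusted p up to 0.0531), Asns (0.0649), Psph (0.0689) and Aldh18a1 (0.0839) were lost, while those of Pck2 and Adm2 and all UVB calls held. Transporters Slc7a5 (0.88 ± 0.11) and Slc7a1 (0.84 ± 0.08) and the tRNA synthetases Eprs1 (0.52 ± 0.07), Cars1 (0.48 ± 0.07) and Wars1 (0.41 ± 0.07) rose with UVB as well, and Cars1 fell with betaine (−0.31 ± 0.07; adjusted p up to 0.107 with 1 array left out).

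A first hypothesis is that UVB raises the amino acid response as a set. Of 38 genes 26 rose and 0 fell (median 0.40; p = 0.00371 with an estimated correlation). Among the 28 members set apart as not seen beforehand 18 rose (median 0.38, camera p = 0.00796 with an estimated correlation). This goes with the hypothesis, but the 28 were not all new. Chac1, Cth and Phgdh had been reported above as rising after UVB, and not all of these were kept out of the 28. All values come from the same arrays. The mirror hypothesis, that betaine lowers the set, gave 10 falls and 0 rises in 38 (p = 0.0257 with an estimated correlation), but 2 falls in those 28 members (p = 0.0705 with an estimated correlation), which leaves it undecided.

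Another hypothesis is that betaine, an osmolyte, lowers genes that hypertonicity raises. Akr1b1, Hspa4l, Slc5a3, Sgk1, Ranbp3l (−1.74) and Fxyd2 (−1.24) fell with betaine averaged. These were the 6 falls among the 14 genes in the full set (p = 9.0e-04 with an estimated correlation). This rests on genes seen first, with Ranbp3l and Fxyd2 among the largest falls with betaine averaged. The 7 members left once those seen first were set aside held 0 falls (p = 0.878 with an estimated correlation). All 6 falls were among the members set aside, so that count was partly fixed by the choice. The data do not decide the hypothesis.

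Arrays of 1 group differ along a leading component that holds 37.9 percent of the within-group variation, with control A (0.44) and betaine C (0.58) at 1 end and betaine B (−0.445) at the other. Whether the degree of late differentiation is what varies stays open. The median loading of the 29 late differentiation genes (−0.0112) lay at percentile 0 of 10000 random lists, but the residuals of those genes correlate (0.4501), which random lists do not share, so a list that varies together would stand out whatever drives the component. By the median of those genes control A stands at −0.32, UVB C at −0.169 and betaine + UVB C at −0.176, but betaine C, with the highest score, at −0.024. Its loadings correlate across genes at 0.513 with the change in betaine + UVB vs UVB, 0.423 with the interaction, 0.397 with betaine + UVB vs control, 0.379 with betaine averaged, 0.325 with betaine + UVB vs betaine, 0.166 with UVB averaged, 0.068 with betaine vs control and −0.052 with UVB vs control; these effects come from the same arrays, and the cause was not tested.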
